A study of Mus musculus with 3 samples.

How the data were processed

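Gene expression was measured in CD8 T cells of mice on 3 one-colour Affymetrix-type arrays, each hybridised with biotin-labelled cRNA made from 6 µg of total RNA, which was extracted with an RNeasy kit per the labels' protocols. The tissue is given as MLN, which in the study is the mesenteric lymph node. Each of the 3 groups, CL4-TCR, VILLIN-HA/CL4-TCR and Villin-HA + CL4-TCR, holds 1 array, and the group was taken from the source name of each sample.

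The deposited values are MAS5 intensity values, per the submitters' processing notes, in which no version is named. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 linear signal and scales the whole array. The values as deposited bear this out in form: they run on a linear scale from 0 to 19538, and the 2% trimmed mean over the 45101 probe sets is 150 on each array. The background settings are not given in the sources used here, and detection calls, which mark single probe sets as present or absent, were not used here. Because every array is scaled to 1 trimmed mean, a shift shared by most transcripts would not appear in these values.

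Probe sets were named through the annotation table of the platform, with symbols updated through Entrez gene identifiers to the GRCm38.p6 RefSeq gene table. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none. The identifier was found in that table for 34754 of those with 1 symbol, and the other 204 kept the name of the annotation table. Probe sets with several symbols were not used to name a gene. The 18193 named genes were each represented by the probe set with the highest mean deposited signal over the 3 arrays, and the other probe sets of the gene served to show where probe sets disagreed. Probe positions and a genome sequence were not used here.

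A floor was set at the median of all values of the 3 arrays, a signal of 31.7, and lower values were raised to it. A gene was measured in a comparison where the higher of its values lay above the floor, and it was counted as higher or lower where the log2 difference was at least 1 in size, a fold of 2. Where the lower value lay at the floor, the fold is a lower bound and is written as at least that many fold. With 1 array per group there is no replicate spread, so no p-value, standard error or standard deviation between samples is given, and every difference is one between arrays and not shown to be one between conditions. The number of arrays limits the precision. The disagreement between probe sets of 1 gene served as the only measure of error. It is given as the SD of the log2 differences of probe sets above the floor on both arrays. It covers probe and labelling effects but not animals or sorts.

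The comparisons were VILLIN-HA/CL4-TCR minus CL4-TCR, Villin-HA + CL4-TCR minus CL4-TCR, and VILLIN-HA/CL4-TCR minus Villin-HA + CL4-TCR. Before the data were examined, 28 gene lists with 393 different gene names were fixed, of which 354 names were found among the named genes. They cover genes associated with regulatory CD4 T cells, inhibitory receptors and exhaustion, naive and memory cells, cytotoxic effectors, activation, anergy, proliferation, gut homing and residency, chemokines, the TNF superfamily, cytokine receptors, the TGF-beta response, interferon-induced genes, immediate-early and stress genes, glycolysis, CD8 T cell identity, housekeeping genes, sex-linked genes, and markers of CD4 T cells, B cells, plasma cells, NK cells, myeloid and dendritic cells, gamma delta T cells, epithelium, stroma and endothelium, and erythroid cells. One of the 28 holds Itgae, Nrp1, Tnfrsf9 and Pdcd1, which the study is known to have picked from these arrays, and it is not independent evidence. These genes also count in other lists: Pdcd1 under inhibitory receptors, Tnfrsf9 under activation and the TNF superfamily, and Itgae under gut homing and the TGF-beta response. Lists share other genes too, such as Il2ra, Tnfrsf4 and Icos (regulatory and activation), Ctla4 and Entpd1 (regulatory and inhibitory) and Egr2 and Egr3 (anergy and activation). Results of such lists are not separate from each other. Another 3 lists, of stromal, skeletal muscle and neutrophil transcripts, were written after the data had been seen and before the values of their members were read, apart from Acta1 and Atp2a1 of the muscle list.

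The median log2 difference of each list was set beside the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. Its percentile among them describes these arrays and is not a test of conditions. Since 2 comparisons share the CL4-TCR array, the overlap of their counted genes was set beside n1 × n2 / N and beside 100 simulations of unchanged arrays, with noise drawn in 50 signal bins from the difference between the arrays of the other groups. That noise contains real differences between those arrays, so it may be too large, and noise particular to the CL4-TCR array was not measured.

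The genes named were chosen by a rule fixed before the data were examined. It takes, in each comparison, the 10 highest and 10 lowest among genes above the floor on both arrays whose probe sets above the floor on both arrays differed in 1 direction, the 5 largest bounds each way, up to 4 members of each list with the largest difference, and all 4 genes picked by the study. Clones without a gene name were counted and not named. Some further list members are named as examples, chosen after their values were seen, as are those of the 3 later lists.

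The counting was tested on simulated data for VILLIN-HA/CL4-TCR against CL4-TCR, run on 18193 genes with a noise SD of 0.25 per array on the log2 scale. That SD was chosen, and the 0.354 it gives for a difference lies below the measured SD between probe sets of 0.43, 0.65 and 0.61 in the 3 comparisons. In this and the following runs, the genes simulated as changed were drawn only from those with a mean signal well above the floor. Recovery of dim genes, such as many of those given as bounds, was therefore not tested. The simulated noise was the same at all signals. The counting recovered 96 of 100 genes simulated at a log2 difference of 1.5 and 100 of 100 at 3.0, and it counted 40 of 10893 unchanged genes, or 0.37%. With noise that gave differences the measured SD, run on the same 18193 genes, it recovered 93, 76 and 81 of 100 at 1.5 and 100 of 100 at 3.0 in the comparisons in that order, and it counted 235 of 10949, 1225 of 11192 and 1031 of 11185 unchanged genes.

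Of the alternatives, 7 were planned: scaling every array to the same median, quantile normalization, a floor at the 25th percentile (a signal of 9) or the 65th percentile (68.6), a pseudocount of the median in place of the floor, the mean over all probe sets of a gene, and leaving out probe sets whose identifiers end in _s_at or _x_at, which can match several transcripts. A further 2, leaving out genes on X and Y and counting a gene only where all its measured probe sets differed in 1 direction, were chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.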

Results

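Gene expression was compared between 3 populations of mouse CD8 T cells, with 1 array for each. CL4-TCR mice carry a transgenic T cell receptor that makes CD8 T cells recognise hemagglutinin (HA), a surface protein of influenza virus. VILLIN-HA/CL4-TCR and Villin-HA + CL4-TCR combine these T cells with HA placed under the promoter of villin, a protein of gut epithelial cells, so that the antigen is made in the gut. The submitters list an ordinary, an activated and a regulatory population, the latter pair formed in the animal, and the sample labels do not say which of the 2 HA arrays is the activated and which the regulatory one. In the study as known apart from the labels, suppressive CD8 T cells came from mice that carried both transgenes.

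Each array reported 45101 probe sets as MAS5 signal with a trimmed mean of 150. The median signal was 30.6 on the CL4-TCR array, 29.4 on the VILLIN-HA/CL4-TCR array and 35.3 on the Villin-HA + CL4-TCR array, and 10270, 10341 and 11421 genes lay above the floor of 31.7. The Gapdh control probe sets, which compare the ends of 1 transcript, had 3′ to 5′ signal ratios of 18.4, 46.2 and 3.35 in the same order. For 9 probe sets of added control RNA, the median log2 difference from the CL4-TCR array was -0.04 on the VILLIN-HA/CL4-TCR and 0.42 on the Villin-HA + CL4-TCR array. No group had a replicate, so the differences below are between single arrays, and the labels give no batch, so a batch of labelling or hybridisation would not be separated from the group. A gene is called higher or lower at a difference of at least 2-fold, and a gene is measured in a comparison if it lay above the floor on either array.

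All 3 arrays carried transcripts of CD8 T cells at high signal. Cd8a, a chain of the CD8 co-receptor, had signals of 2714, 2893 and 3149 on the CL4-TCR, VILLIN-HA/CL4-TCR and Villin-HA + CL4-TCR arrays, and Ptprc, the leukocyte antigen CD45, had 11134, 11459 and 11082. Cd4 lay below the floor on each, as did Vil1, the villin gene of gut epithelium. Of 15 measured CD8 identity genes, 2 were lower on the VILLIN-HA/CL4-TCR array than on the CL4-TCR array, Lat (3.72-fold) and Cd2 (3.23-fold), both parts of T cell signalling and adhesion, and none was counted on the Villin-HA + CL4-TCR array. Of 10 housekeeping genes, only Polr2a, the large subunit of RNA polymerase II, was counted, with a log2 difference of -1.32 on the Villin-HA + CL4-TCR array against the CL4-TCR array. Gapdh is not among these 10. Its control probe sets had log2 differences of 1.37 at the 3′ end and 3.83 at the 5′ end between the same arrays, and those of Actb had 0.37 and 0.51.

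The arrays differed in sex-linked transcripts, so effects of the sex of the mice are not separated from those of the group. Xist, the RNA that coats the inactive X chromosome of female cells, had a signal of 5442.5 on the CL4-TCR array, 2.5 on the VILLIN-HA/CL4-TCR array and 1339 on the Villin-HA + CL4-TCR array. The Y-linked gene Eif2s3y had 13.4, 1496 and 747, and Kdm5d had 0.8, 402 and 136. By these transcripts, the RNA was mainly female on the CL4-TCR array and mainly male on the VILLIN-HA/CL4-TCR array. A comparison of these arrays is thus also one between the sexes. By their chosen probe sets, Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty lay above the floor together on the Villin-HA + CL4-TCR array alone. Of the 3 Xist probe sets, another one, which can match several transcripts, was also above the floor on the VILLIN-HA/CL4-TCR array, at a signal of 66.3 or 1.96% of its 3379 on the CL4-TCR array, and all 3 were above it on the Villin-HA + CL4-TCR array.

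The first comparison, of VILLIN-HA/CL4-TCR with CL4-TCR, asks how HA-specific CD8 T cells from mice with HA in the gut differ from those of mice without it. Cell cycle genes were higher on the VILLIN-HA/CL4-TCR array: 27 of 31 measured proliferation genes were higher and none lower, with a median log2 difference of 2.34 against -0.28 to 0.25 in 95% of random lists. Mki67, a marker of cycling cells, was at least 69.3-fold higher, and Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, was 37.7-fold higher. Transcripts of naive and recirculating T cells were lower, with 10 of 17 lower and none higher and a median of -1.42. Igfbp4, which is abundant in naive T cells, was 16.2-fold lower, and Klf2, a transcription factor that keeps T cells recirculating, was 5.69-fold lower.

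The 4 genes that the study picked from these arrays were all higher, which is not independent evidence. Tnfrsf9, the costimulatory receptor 4-1BB, was 16.1-fold higher, Pdcd1, the inhibitory receptor PD-1, 11.5-fold, Nrp1, a receptor found on regulatory CD4 T cells, 10.4-fold, and Itgae, the CD103 integrin chain that binds E-cadherin, 6.75-fold. These folds are by the chosen probe sets, and the measured probe sets of Nrp1 ranged from 1.40 to 3.38 and those of Tnfrsf9 from 2.16 to 4.01 on the log2 scale. Of 19 measured genes associated with regulatory CD4 T cells, a list that holds 3 of those 4, 11 were higher and none lower (median 1.30). Ikzf2, which encodes Helios, was 16.0-fold higher and Ctla4, an inhibitory receptor, at least 14.2-fold. Foxp3, the lineage factor of regulatory CD4 T cells, had a signal of 38.2 against 29.6, and Il10 lay below the floor on all 3 arrays.

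Inhibitory receptors and exhaustion genes were higher for 8 of 13 measured members, with a median of 3.09, and the study-picked Pdcd1 is among the 8. Cd160 was 21.7-fold higher by its chosen probe set, with measured probe sets from 1.13 to 4.44 on the log2 scale. Nr4a1, a nuclear receptor induced by T cell receptor signals, was 15.1-fold and Lag3 at least 8.49-fold higher, while Eomes, a T-box factor of memory CD8 T cells, was 5.38-fold lower. Activation genes were higher for 16 of 24 and lower for none (median 1.77), among them the chemokine gene Xcl1 (at least 33.7-fold), Cd83 (at least 25.6-fold) and Irf4 (17.9-fold). Of 14 anergy genes, 5 were higher, including Egr2 (7.79-fold), a factor that limits T cell responses, and 1 was lower, Socs3 (8.32-fold), an inhibitor of cytokine signalling. Egr3 was 6.91-fold higher by its chosen probe set, and its other measured probe set had a log2 difference of -0.62.

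Cytotoxic effector genes differed less as a group, with 6 of 22 measured members higher, 3 lower and a median of 0.56, which became -0.04 with the floor at the 65th percentile. The granzyme genes Gzma and Gzmb, whose products kill target cells, had log2 differences of -0.11 and at least 0.64, Klrd1, an NK receptor chain, was 12.0-fold lower and Prf1, which encodes perforin, 5.31-fold lower by its chosen probe set. The other probe set of Prf1 had a log2 difference of -0.95, short of 2-fold. Ccl5 was 4.30-fold and Ccl4 3.64-fold higher, both being chemokine genes of activated T cells. Interferon-induced genes had 1 of 23 higher, 3 lower and a median of -0.67, below all random lists. Oas2 was 4.06-fold lower and Ifi27l2a 4.06-fold higher. Immediate-early and stress genes had 2 of 16 higher, Fos (15.2-fold) and Dusp1 (3.11-fold), and 2 lower, with a median of -0.12.

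Among the other lists, 8 of 17 TNF superfamily genes were higher and 1 lower, with Tnfsf11, the cytokine RANKL, at least 12.2-fold higher. Of 15 chemokine and receptor genes, 6 were higher and 3 lower, Cxcr4 by 7.52-fold. Gut homing and residency genes went both ways, with 4 of 12 higher and 3 lower. Ahr, the aryl hydrocarbon receptor, was at least 7.17-fold higher by its chosen probe set and Itgb7, a gut-homing integrin chain, 3.87-fold lower. The other measured probe set of Ahr had a log2 difference of at least 0.565. Cytokine receptor and signalling genes had 1 of 23 higher and 6 lower, with Il18r1 7.10-fold and Il7r, the survival receptor for interleukin 7, 4.06-fold lower. Of 11 genes of the TGF-beta response, 2 were higher, Tgfbi and the study-picked Itgae, and 2 lower, Smad7 and Ski, inhibitors of that pathway. The measured probe sets of Tgfbi ranged from 0.02 to 1.38 on the log2 scale. Glycolysis genes had 4 of 12 higher, led by Hk2 (4.02-fold), which encodes a hexokinase. Of 9 measured myeloid and dendritic cell markers, 4 were higher on the VILLIN-HA/CL4-TCR array and none lower: the lysozyme gene Lyz2 (9.67-fold), Csf1r, the macrophage growth factor receptor gene (9.39-fold), the complement gene C1qb (at least 4.69-fold) and Tyrobp (2.22-fold). The measured probe sets of Csf1r ranged from 0.33 to 3.23 on the log2 scale.

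Across all genes, 837 were higher and 746 lower on the VILLIN-HA/CL4-TCR array, which is 14.1% of 11259 measured, and 246 of the higher and 91 of the lower differences were bounds. The largest measured differences outside the groups above included Pclaf (23.4-fold), Cdca5 (22.5-fold) and Cdca8 (20.1-fold), further genes of DNA replication and mitosis, and Endod1 (23.3-fold). Among the lower were St3gal6 (8.50-fold), Tent5a (8.37-fold), Wnt5b (7.68-fold) and App (7.15-fold) by their chosen probe sets. St3gal6, Wnt5b and App each had a measured probe set short of 2-fold, with log2 differences of -0.38, -0.95 and -0.87. Lyz1 was 24.6-fold higher by a probe set that can match other transcripts, and its log2 difference was -0.12 without such probe sets. Probe sets of 1 gene differed by an SD of 0.43 on the log2 scale, pooled over 4174 genes. Of 481 called genes with several probe sets above the floor on both arrays, 411 had all of these in 1 direction. In simulated unchanged arrays with differences of that SD, 235 of 10949 genes passed 2-fold. With every array scaled to the same median, 59.2% of the calls were higher instead of 52.9%.

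**Figure D1:**
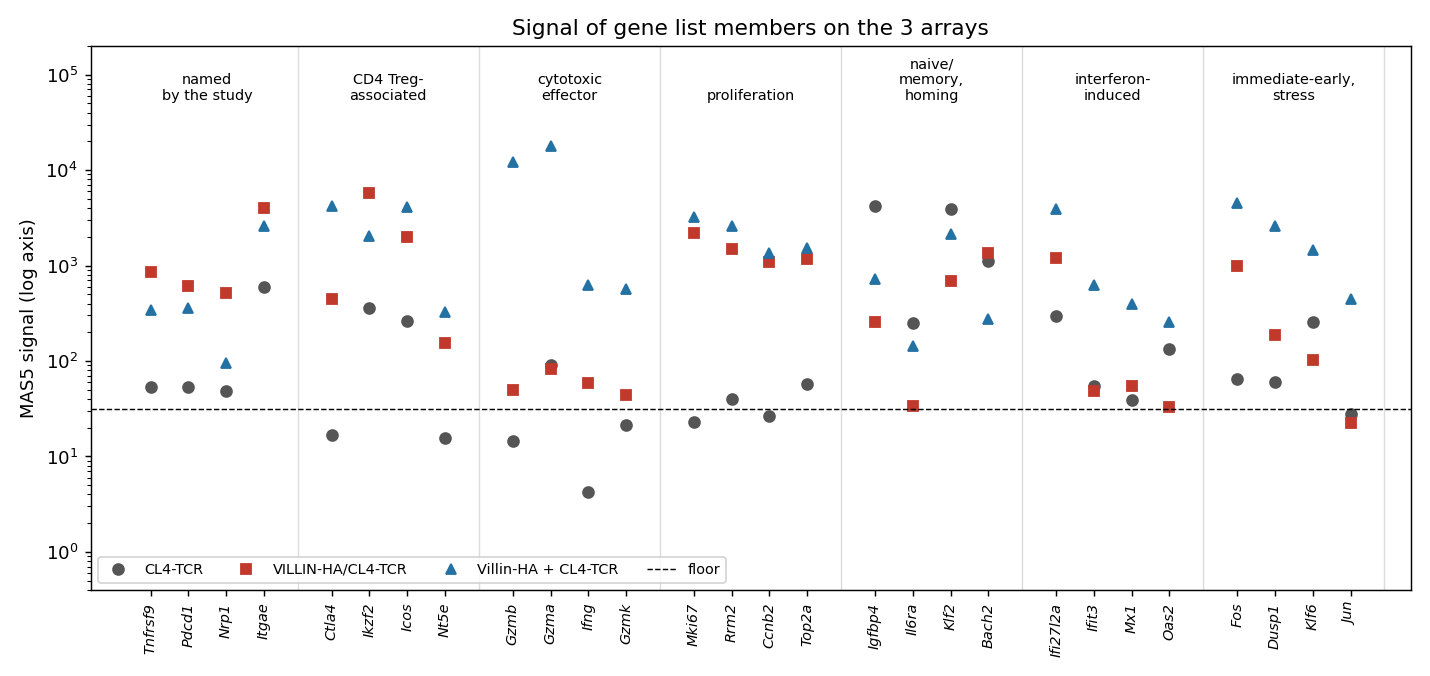
Signal on a log axis of up to 4 genes from each of 7 lists on the CL4-TCR, VILLIN-HA/CL4-TCR and Villin-HA + CL4-TCR arrays, 1 point per array, with the floor of 31.7 as a dashed line. Gzma reaches 18077 on the Villin-HA + CL4-TCR array and stays at 90.1 and 83.3 on the others, while Mki67 is at 2197 and 3191 on the HA arrays and at 22.8 on the CL4-TCR array.

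The second comparison set Villin-HA + CL4-TCR against CL4-TCR and addresses the other HA-exposed population. Genes of killing and of cell division stood far above the CL4-TCR array. Gzmb was at least 381-fold and Gzma 201-fold higher, and 15 of 25 measured cytotoxic effector genes were higher against 1 lower, Prf1 (2.53-fold), with a median of 1.57. Proliferation genes were higher for 30 of 31, with a median of 3.03, including Mki67 at least 100.7-fold and Rrm2 64.8-fold. Interferon-induced genes were higher for 14 of 25 and lower for none (median 1.15), and naive and recirculating genes were lower for 8 of 17 and higher for none (median -0.99).

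Further effector genes on this array were Ifng, the cytokine interferon gamma (at least 19.9-fold), Gzmk (at least 18.1-fold) and Klrc1, an inhibitory NK receptor gene (at least 17.0-fold). Among interferon-induced genes, Ifi27l2a was 13.2-fold, Ifit3 11.5-fold and the antiviral GTPase gene Mx1 10.1-fold higher. Immediate-early and stress genes were higher for 11 of 20 and lower for none (median 1.22), with Fos 70.3-fold, Dusp1 43.2-fold and Jun at least 14.2-fold higher. Fos and Jun encode the partners of the AP-1 transcription factor. Of the naive genes, Igfbp4 was 5.82-fold lower, and Klf3 and Bach2 were 4.24-fold and 4.08-fold lower by their chosen probe sets while another probe set of each gene differed slightly the other way. Ccr7, which guides T cells into lymph nodes, had a log2 difference of 0.44.

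Genes associated with regulatory CD4 T cells were higher for 16 of 20 measured members and lower for none, with a median of 2.18. Ctla4 was at least 132-fold, Icos, a costimulatory receptor gene, 15.7-fold and Nt5e, which encodes the adenosine-producing enzyme CD73, at least 10.3-fold higher. Foxp3 had a signal of 86.4 against 29.6, at least 2.73-fold. Of the 4 genes picked by the study, 3 were higher, Pdcd1 (6.70-fold), Tnfrsf9 (6.44-fold) and Itgae (4.37-fold), and Nrp1 had a ratio of 1.97. The measured probe sets of Tnfrsf9 ranged from 0.63 to 2.69 and those of Nrp1 from -0.15 to 0.98 on the log2 scale. That list is not independent evidence. Inhibitory receptor and exhaustion genes were higher for 11 of 14, with Cd160 27.1-fold higher by its chosen probe set and Eomes, the 1 lower member, 10.9-fold lower. The measured probe sets of Cd160 ranged from 1.19 to 4.76 on the log2 scale. Nr4a2 was at least 57.5-fold higher by its chosen probe set, while its measured probe sets ranged from -0.25 to 5.85 on the log2 scale.

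Activation genes were higher for 19 of 24 and lower for none (median 1.72), among them Bhlhe40, a transcriptional regulator induced in activated T cells (at least 76.8-fold). Gut homing and residency genes were higher for 10 of 13 and lower for none, with Rgs1, a regulator of chemokine receptor signals that is high in resident T cells, 70.8-fold higher. Chemokine and receptor genes had 8 of 15 higher, including Cxcl10 (13.1-fold) and Ccr2 (at least 9.74-fold), and the TNF superfamily had 11 of 18 higher and 1 lower. Anergy genes had 4 of 14 higher, cytokine receptor genes 4 of 25 higher and 4 lower, and TGF-beta response genes 3 of 11 higher and 3 lower, Ski by 5.08-fold. Of 13 glycolysis genes, 6 were higher and none lower, including Tpi1 (7.42-fold), a central enzyme of the pathway.

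Transcripts of cell types other than T cells were higher on this array too, as some myeloid markers were on the VILLIN-HA/CL4-TCR array. Of 6 measured genes of stroma and endothelium, 4 were higher than on the CL4-TCR array, among them the collagen genes Col1a2 (10.2-fold) and Col3a1 (at least 5.71-fold). Myeloid markers were higher for 8 of 13, with S100a8, an abundant neutrophil transcript, at a signal of 739 against 9.5 on the CL4-TCR array. Lyz2 and Csf1r had signals of 312 and 125 here, 817 and 384 on the VILLIN-HA/CL4-TCR array and 84.5 and 40.9 on the CL4-TCR array. Of 15 skeletal muscle genes, a list written after the data were seen, 13 were higher, and the myosin gene Myh1 had a signal of 2100 against 8.1. In 17 further stromal genes and 9 measured neutrophil genes, also from later lists, 5 and 6 were higher.

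Across all genes, 1453 were higher and 1162 lower on the Villin-HA + CL4-TCR array than on the CL4-TCR array, 21.4% of 12195 measured, and 531 of the higher and 130 of the lower differences were bounds. Ifitm3 (47.5-fold) and Ifitm1 (at least 96.8-fold), which encode interferon-induced membrane proteins, and the galectin genes Lgals1 (38.0-fold) and Lgals3 (at least 98.7-fold) were among the largest. Pclaf was 32.9-fold and Tox2 41.1-fold higher by the chosen probe set, and Tox2 had a log2 difference of 0.84 without probe sets that can match several transcripts. Among the lower genes were Ramp1 (18.9-fold) and Calcrl (8.66-fold), which together form a receptor for the neuropeptide CGRP, Sema4a (13.1-fold) and Atp1b1 (10.3-fold). Probe sets of 1 gene differed by a pooled SD of 0.65 on the log2 scale. Of 879 called genes with several probe sets above the floor on both arrays, 595 had all of these in 1 direction. Unchanged arrays simulated with that SD had 1225 of 11192 genes past 2-fold. Scaling every array to the same median turned the share of calls that were higher from 55.6% to 38.3% and moved the median difference of genes above the floor on both arrays from -0.04 to -0.23, and quantile normalization left the share at 55.4%.

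**Figure D2:**
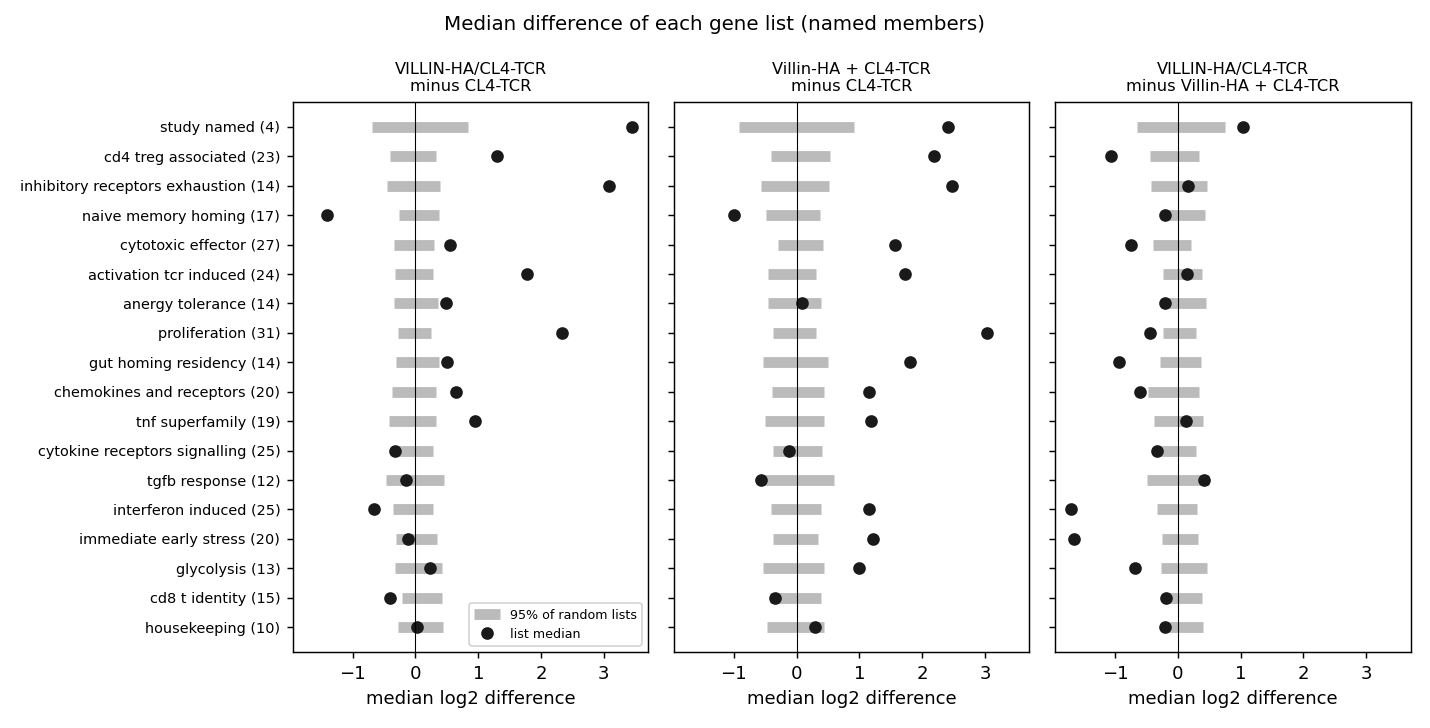
Median log2 difference of each of 18 gene lists in the 3 comparisons (points) with the range of 95% of random lists matched on expression (grey bars), and the number of named members in brackets. Proliferation lies at 2.34 and 3.03 in the comparisons with CL4-TCR, and interferon-induced genes lie at -0.67, 1.15 and -1.69.

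A last comparison set the 2 HA arrays against each other, VILLIN-HA/CL4-TCR minus Villin-HA + CL4-TCR. The VILLIN-HA/CL4-TCR array was lower in many cytotoxic effector, interferon-induced and immediate-early genes. Gzmb was 245-fold and Gzma 217-fold lower, and 13 of 27 measured cytotoxic effector genes were lower against 2 higher (median -0.75). Interferon-induced genes were lower for 18 of 25 and higher for none (median -1.69), and immediate-early and stress genes were lower for 12 of 20 and higher for none (median -1.65). Proliferation genes were closer, with 6 of 31 lower, none higher and a median of -0.44.

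Beside the granzymes, Klrc1 was at least 17.0-fold, Gzmk 13.1-fold and Klrk1, which encodes the activating receptor NKG2D, 12.8-fold lower on the VILLIN-HA/CL4-TCR array. The 2 higher cytotoxic list members were Ccl4 (4.16-fold) and Gzmm (at least 2.08-fold). Ifit3 was 12.7-fold, Oas2 7.69-fold and Mx1 7.12-fold lower. Klf6 was 14.2-fold, Jun at least 14.2-fold and Dusp1 13.9-fold lower. Glycolysis genes were lower for 5 of 13 and higher for none, with Pkm, a pyruvate kinase gene, 3.15-fold lower.

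Nrp1 was 5.30-fold and Tnfrsf9 2.49-fold higher on the VILLIN-HA/CL4-TCR array, Pdcd1 and Itgae had log2 differences of 0.77 and 0.63, and these 4 study-picked genes are not independent evidence. The measured probe sets of Nrp1 ranged from 1.10 to 2.41 and those of Tnfrsf9 from -0.63 to 1.47, and averaged over its probe sets Tnfrsf9 had 0.72. Of 20 measured genes associated with regulatory CD4 T cells, 3 were higher, Nrp1, Ikzf2 (2.84-fold) and Tnfrsf9, and 11 were lower, including Ctla4 (9.30-fold), Capg (3.47-fold) and Foxp3 (2.26-fold), with a median of -1.06. Inhibitory receptor and exhaustion genes had 2 of 14 higher and 5 lower, and Cd160 and Lag3 had log2 differences of -0.32 and -0.21.

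Activation genes split, with 8 of 24 higher and 7 lower. Egr2 was 8.21-fold, Xcl1 3.62-fold and Irf8 2.82-fold higher, and Bhlhe40 was 10.2-fold lower. Anergy genes had 3 of 13 higher and 2 lower. Naive and recirculating genes had 2 of 17 higher and 6 lower, with Il6ra 4.29-fold and Ccr7 3.63-fold lower, and the list median of -0.21 became 0.06 when arrays were scaled to the same median. Gut homing and residency genes were lower for 7 of 14 and higher for none, among them Rgs1 (17.5-fold), Cxcr3 (8.22-fold) and Cxcr6 (8.05-fold), the last 2 being chemokine receptors of effector and resident T cells. Chemokine and receptor genes had 2 of 15 higher and 7 lower, the TNF superfamily 4 of 18 higher and 2 lower, cytokine receptor genes 2 of 25 higher and 8 lower, and TGF-beta response genes 2 of 11 higher and 1 lower.

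Markers of some other cell types were lower here as well: stroma and endothelium for 4 of 6, skeletal muscle for 13 of 15, the further stromal genes for 6 of 15 and neutrophil genes for 6 of 9, with none higher. B cell, plasma cell and CD4 T cell markers each had 2 members higher and none lower. Myh1 was at least 66.2-fold, Acta1, the actin of skeletal muscle, 28.6-fold and S100a8 at least 23.3-fold lower on the VILLIN-HA/CL4-TCR array. Myeloid markers went both ways, with 3 of 14 higher and 5 lower. Csf1r was 3.07-fold and C1qb 3.33-fold higher.

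Across all genes, 741 were higher and 1080 lower on the VILLIN-HA/CL4-TCR array, 15.1% of 12080 measured, and 93 of the higher and 313 of the lower differences were bounds. Among the largest were Ifitm1 (at least 96.8-fold lower), Ifitm3 (39.9-fold lower), S100a6 (26.1-fold lower), Plac8 (13.6-fold lower) and, on the other side, Ramp1 (11.6-fold higher), Trat1 (9.78-fold higher), Id3, an inhibitor of E proteins (9.71-fold higher), and Dnmt3a, a DNA methyltransferase gene (5.95-fold higher). Sox4 was 20.3-fold higher by its chosen probe set, and its measured probe sets ranged from 0.27 to 4.35 on the log2 scale. The share of calls that were higher was 40.7%, and it became 67.1% when arrays were scaled to the same median, which moved the median difference of genes above the floor on both arrays from 0.02 to 0.26. Probe sets of 1 gene differed by a pooled SD of 0.61, and 1031 of 11185 genes passed 2-fold in unchanged arrays simulated with that SD. Of 554 called genes with several probe sets above the floor on both arrays, 346 had all of these in 1 direction.

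Many genes differed from CL4-TCR in the same direction on both HA arrays. Of 10939 genes measured in both comparisons, 537 were higher on both, which is 65.7% of 817 and 42.4% of 1268, and 339 were lower on both, 45.4% of 746 and 29.2% of 1162. Asking for both took the higher genes from 837 to 817 and from 1453 to 1268. It removed no lower gene, since these lay above the floor on the CL4-TCR array, so the higher and lower shares rest on unlike filters. Mki67, Rrm2, Cd160, Cd83 and Icos were among those higher on both, and Igfbp4, Txk, Eomes and Il18r1 among those lower on both. Independent lists of these sizes would share 94.7 and 79.2 genes, and simulated unchanged arrays that share the CL4-TCR array shared 278 and 544 on average. The simulated noise holds the real differences between the HA arrays, so it may be too large, and noise particular to the CL4-TCR array was not measured. For VILLIN-HA/CL4-TCR against CL4-TCR, the simulations counted 923.5 genes higher and 1106.9 lower on average, against 817 and 746 in the data. The overlap of higher genes lay above the 313 that the simulations reached at most, and part of it may come from the shared array. That of lower genes lay below the simulated mean, so the simulations cannot tell it apart from an effect of the shared array. In opposite directions, 4 genes were higher on the VILLIN-HA/CL4-TCR and lower on the Villin-HA + CL4-TCR array, Sox4, Trat1, Id3 and Dnmt3a, and 23 were lower on the first and higher on the second.

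B cell markers had 5 of 12 measured members higher on the VILLIN-HA/CL4-TCR and 4 of 12 on the Villin-HA + CL4-TCR array than on the CL4-TCR array, including H2-Eb1, an MHC class II gene (2.73-fold and 4.16-fold), while Cd79a lay below the floor on all arrays. The immunoglobulin gene Ighm had signals of 3005, 2666 and 1913 on the CL4-TCR, VILLIN-HA/CL4-TCR and Villin-HA + CL4-TCR arrays. Between the HA arrays, 2 of 12 B cell markers were higher on the VILLIN-HA/CL4-TCR array. Over the comparisons in the order given, plasma cell markers had 2, 1 and 2 of 4 higher, CD4 T cell markers had 2 of 4, 1 of 4 and 2 of 3 higher, with Trat1 lower on the Villin-HA + CL4-TCR array than on the CL4-TCR array, and NK markers had 1 of 3, 2 of 5 and 1 of 5 higher and 1 lower in each. The NK markers counted were only Gzma, Eomes and Tyrobp, which also stand in the cytotoxic, exhaustion and myeloid lists. Ncr1 and Klra8 lay below the floor on all arrays, and Klre1 was counted in no comparison. Gamma delta T cell markers had only Zbtb16 counted, higher on the Villin-HA + CL4-TCR array than on either other array. No epithelial or erythroid marker was counted in any comparison.

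**Figure D3:**
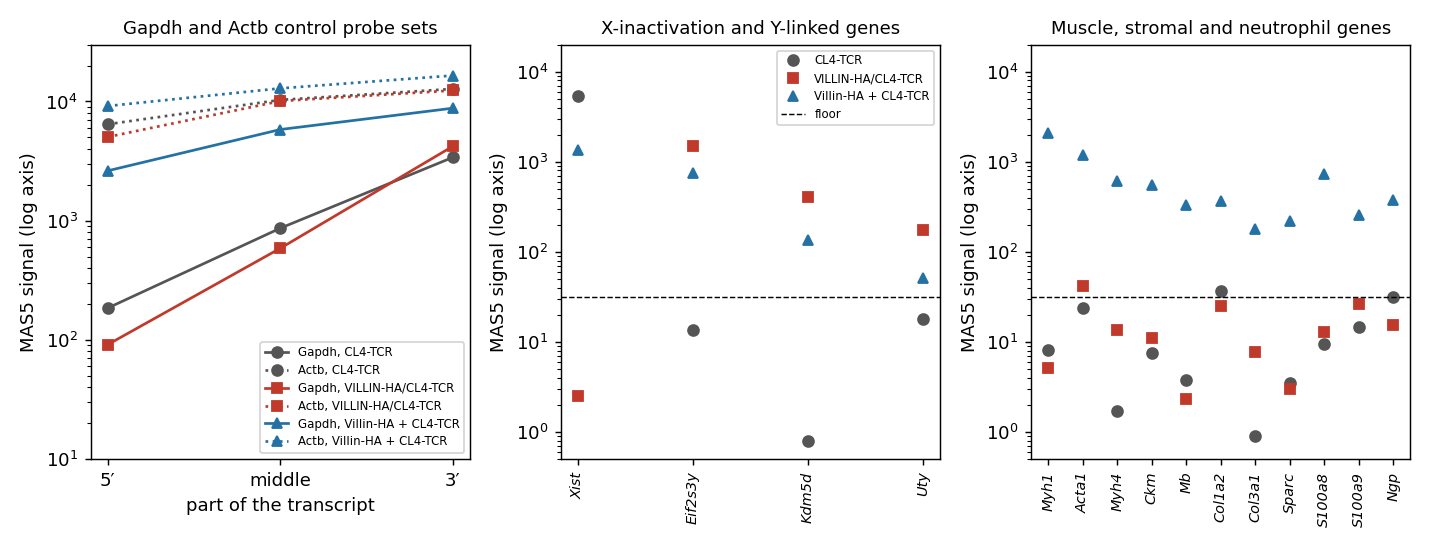
Signal on a log axis, 1 point per array, of Gapdh and Actb control probe sets by transcript part (left), of Xist and Y-linked genes (middle) and of muscle, stromal and neutrophil genes (right). The Gapdh signal falls from 4212 at the 3′ end to 91.2 at the 5′ end on the VILLIN-HA/CL4-TCR array and from 8787 to 2621 on the Villin-HA + CL4-TCR array, and Xist and Eif2s3y are both above the floor on the latter.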

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

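Among the tests used here, those on the X and Y chromosomes and on 3′ bias were chosen before their results were seen, and the alternatives that leave out genes were chosen after seeing the data.

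On the VILLIN-HA/CL4-TCR array the Gapdh control probe sets had a 3′ signal 46.2 times the 5′ signal, in data that the comparisons of genes did not use, against 18.4 on the CL4-TCR array and 3.35 on the Villin-HA + CL4-TCR array. The ratio for Actb was 2.46, 1.98 and 1.80 in the same order.

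The number of genes at least 2-fold apart, 1583, 2615 and 1821 in the 3 comparisons, was weighed against technical sources. At most 3.67% of the counted genes lay on the X and Y chromosomes, so transcripts located there made up little of the count. Of the measured genes in that comparison, 3.08% lay there, too few to be most of the count whatever their differences. Effects of sex on genes of other chromosomes were not tested. Without genes on X and Y, 793 genes were higher and 732 lower on the VILLIN-HA/CL4-TCR array than on the CL4-TCR array. On the Villin-HA + CL4-TCR array, 1405 were higher and 1139 lower. Unequal 3′ bias of the labelled RNA may account for part of the count: the median disagreement between probe sets of a gene was 1.46 times as large between the HA arrays as between VILLIN-HA/CL4-TCR and CL4-TCR, but it was 0.44 between Villin-HA + CL4-TCR and CL4-TCR and 0.43 between the HA arrays, which is not the order of the Gapdh ratios, so the bias and a difference between the cells cannot be told apart. The antigen exposure that the groups differ in stays open and untested. So does an effect of the sex of the mice, which the labels do not give and which cannot be told apart from the group. Xist had signals of 5442.5 and 2.5 on the CL4-TCR and VILLIN-HA/CL4-TCR arrays, and Eif2s3y had 13.4 and 1496. By these transcripts the former array held mainly female and the latter mainly male RNA. A labelling or hybridisation batch stays open as well, since the labels do not give it and 1 array per group would not separate it from the group. This concerns the Villin-HA + CL4-TCR array, with its added control RNA 0.42 higher on the log2 scale and its Gapdh ratio of 3.35.

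The comparisons of genes left out 9160 probe sets without a gene name outside the controls. Of these, 4206 lay above the floor on any of the arrays. Among them, 54 were at least 2-fold higher on both HA arrays than on the CL4-TCR array, and 136 were lower on both. Both counts rest on the same CL4-TCR array, and no value for unchanged arrays was set beside them.

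Several named genes went opposite ways on the HA arrays against the CL4-TCR array, and the difference was not tested, since each group holds 1 array. Higher on VILLIN-HA/CL4-TCR and lower on Villin-HA + CL4-TCR were Sox4, Trat1, Id3 and Dnmt3a, with log2 differences between those arrays of 4.35, 3.29, 3.28 and 2.57. In the other direction were Klf6 (-3.83), Plac8 (-3.76), Rgs2 (-3.51), Il18rap (-3.04), Cxcr3 (-3.04), Hspa1b (-2.93) and Irf7 (-2.33). For Sox4, another measured probe set had 0.27, and for Klf6 against CL4-TCR on the VILLIN-HA/CL4-TCR array the probe sets ranged from -1.40 to 0.26. In that comparison, those of Trat1 ranged from 0.55 to 1.51 and those of Hspa1b from -1.68 to -0.22.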

How the results depend on the processing

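Of the settings below, leaving out X and Y genes and requiring all probe sets of a gene in 1 direction were chosen after seeing the data, and the others before. The cause of each shift was not tested unless the setting itself gives it. A floor at the 25th percentile measures more dim genes and raised the higher and lower counts to 1915 and 1913 (VILLIN-HA/CL4-TCR against CL4-TCR), 3197 and 2046 (Villin-HA + CL4-TCR against CL4-TCR) and 1553 and 2857 (VILLIN-HA/CL4-TCR against Villin-HA + CL4-TCR), and those shared by both HA arrays to 1157 and 739. A floor at the 65th percentile measures fewer genes and left 942 higher on Villin-HA + CL4-TCR than on CL4-TCR and 633 lower on VILLIN-HA/CL4-TCR than on Villin-HA + CL4-TCR. Averaging probe sets left 665 genes lower on Villin-HA + CL4-TCR than on CL4-TCR and 342 higher between the HA arrays, and scaling to the same median gave 1363 higher and 668 lower between the HA arrays. All other counts stayed within 1.5 times the main ones, including those of the 2 later settings. Of the list medians for VILLIN-HA/CL4-TCR against CL4-TCR, genes associated with regulatory CD4 T cells had 1.87 (25th percentile floor) and 0.96 (mean of probe sets), cytotoxic genes 0.75 and 0.27 in these settings and -0.036 with the 65th percentile floor, proliferation 2.75, 1.76 and 1.84 likewise, 2.17 with the pseudocount and 2.20 without _s_at and _x_at probe sets, and interferon-induced genes -0.40 with the mean of probe sets. For Villin-HA + CL4-TCR against CL4-TCR, the 65th percentile floor gave 1.30 for the regulatory list, 2.44 for proliferation and 0.92 for interferon-induced genes, the mean of probe sets gave 1.24 for the regulatory list, 1.22 for cytotoxic genes and 2.18 for proliferation, the 25th percentile floor 1.82 for cytotoxic genes and 3.90 for proliferation, the pseudocount 2.66 for proliferation, and scaling to the same median 0.94 for interferon-induced genes. For VILLIN-HA/CL4-TCR against Villin-HA + CL4-TCR, scaling to the same median gave -0.79 for the regulatory list, 0.057 for naive genes, -0.18 for proliferation and -1.43 for interferon-induced genes, and the mean of probe sets gave -0.78, -0.57 and -1.45 for the regulatory, cytotoxic and interferon-induced lists. Cytotoxic genes had -0.90 with quantile normalization, -1.12 with the 25th and -1.56 with the 65th percentile floor, and interferon-induced genes -1.42 with the 65th percentile floor and -1.35 with the pseudocount. Of 277 differences of named genes past 2-fold, 2 dropped below it with scaling to the same median, 1 with quantile normalization, 0 with the 25th and 17 with the 65th percentile floor, 9 with the pseudocount and 32 with the mean of probe sets, and 8 of 269 did without _s_at and _x_at probe sets, where Lyz1 turned to -0.12 on VILLIN-HA/CL4-TCR against CL4-TCR. By more than the pooled SD between probe sets, 0 of the named differences moved with either scaling. Scaling to the same median shifts genes above the floor on both arrays by 1 amount smaller than that SD, so its 0 was fixed beforehand. By more than that SD, 61 moved with the 25th and 120 with the 65th percentile floor, 80 with the pseudocount and 115 with the mean of probe sets. Without _s_at and _x_at probe sets, 15 did besides Lyz1. Of 29 medians past 2-fold in the lists fixed before the data were examined, 3 dropped below it with scaling to the same median, 1 with quantile normalization, 3 with the 25th and 4 with the 65th percentile floor, 4 with the pseudocount, 7 with the mean of probe sets and 0 without _s_at and _x_at probe sets. The 3 later lists were not run in these settings. No paired analysis was possible because each group holds 1 array, and no replicate could be left out. Signals near the floor limit the folds given as bounds and also measured folds over a dim signal. Rrm2 had 39.8 and Ifitm3 41.4 on the CL4-TCR array, and the 65th percentile floor brought Rrm2 on VILLIN-HA/CL4-TCR from a log2 difference of 5.24 to 4.45 and Ifitm3 on Villin-HA + CL4-TCR from 5.57 to 4.84.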

Other observations

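The gene families here were grouped by symbol after the data had been seen, and the test on sex-linked transcripts was chosen after the result was seen. The other tests were written before their values were read, on lists chosen after seeing the data.

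Of 313 measured zinc finger genes, those with symbols starting in Zfp, Zkscan, Zscan or Zbtb, 76 were at least 2-fold lower on the Villin-HA + CL4-TCR array than on the CL4-TCR array, 13 were higher and the others did not reach 2-fold. Over all genes, 1162 of 12195 were lower and 1453 higher. The family had a median log2 difference of -0.47 that was -0.66 with arrays scaled to the same median and -0.45 with quantile normalization. Against the same array, VILLIN-HA/CL4-TCR had 14 of 311 lower and 9 higher, with a median of -0.12. Between the HA arrays, 63 of 310 were higher on VILLIN-HA/CL4-TCR and 12 lower, with a median of 0.42. The Villin-HA + CL4-TCR array also had the Gapdh 3′ to 5′ ratio of 3.35 against 18.4 on the CL4-TCR array, and the median SD between probe sets of a gene was 0.44 in that comparison and 0.29 between VILLIN-HA/CL4-TCR and CL4-TCR.

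Genes of the proteasome, which degrades tagged proteins, had median log2 differences from the CL4-TCR array of 0.42 on VILLIN-HA/CL4-TCR, with 5 of 38 at least 2-fold higher and 2 lower, and of 0.73 on Villin-HA + CL4-TCR, with 9 of 37 higher and none lower, and both medians kept their sign under both scalings. Between the HA arrays the proteasome median of -0.10 turned to 0.16 with arrays scaled to the same median. Genes of mitochondrial complex I had medians of 0.46 and 0.28 against CL4-TCR, and no more than 2 of 34 were counted. Ribosomal protein genes had medians of -0.01 and 0.17, and both signs turned with arrays scaled to the same median, to 0.04 and -0.04.

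Muscle, stromal and neutrophil transcripts lay above the floor on the Villin-HA + CL4-TCR array and mostly not on the others, and the lists tested here were prompted by such genes, among them Acta1 (1191), S100a8 (739), Col1a2 (370) and Sparc (218), which count in none of the shares below. A general rise of dim signals to at least 2-fold above the floor there is argued against. Of 6934 genes at or below the floor on both other arrays, 2.7% were at least 2-fold higher on the Villin-HA + CL4-TCR array. Signals below the floor were raised to it first, so a rise that left them short of 2-fold above the floor was not tested. This includes a 2-fold rise of signals well below the floor. The median signal was 35.3 there against 30.6 on the CL4-TCR and 29.4 on the VILLIN-HA/CL4-TCR array. RNA of skeletal muscle in that sample is a candidate source, with 84.6% of 13 muscle genes at least 2-fold higher there than on both other arrays and Myh1 at 2100 and Ckm at 555, and so is RNA of neutrophils, with 50% of 12 genes, just at the limit set beforehand, with Ngp at 374 and Ltf at 246 while Csf3r, Cxcr2 and Mmp8 stayed below the floor. Stromal cells stay undecided, with 29.4% of 17 further stromal genes, between the limits set beforehand, with Dcn at 119 and Bgn at 90.7. A sort for CD8 T cells would remove such cells, no sort is described in the labels, and no biological explanation was tested.

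By their chosen probe sets, Xist and Y-linked transcripts were both above the floor on the Villin-HA + CL4-TCR array, while each other array had the one or the other, except that 1 of 3 Xist probe sets reached 66.3 on the VILLIN-HA/CL4-TCR array, 1.96% of its CL4-TCR signal. RNA of mice of both sexes on that array may account for this, since Xist there was 24.6% of its signal on the CL4-TCR array, and Eif2s3y, Kdm5d and Uty were 49.9%, 33.8% and 29.1% of theirs on the VILLIN-HA/CL4-TCR array. The labels do not give the sex of the mice or the number pooled. Cells moved from a donor mouse into a host of the other sex, with host cells among those collected, would give these values as well, and the data used here do not separate that from a pool of mice.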
